A study of Bos taurus with 6 samples.

How the data were processed

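Poly(A) RNA of the longissimus dorsi, the long muscle of the back, was sequenced from 6 male Hanwoo (Korean cattle), with 1 library per animal. Per the labels' protocols, total RNA was isolated with Trizol and an RNeasy kit with DNase treatment, mRNA was selected with oligo-dT beads, and TruSeq libraries were made for an Illumina NextSeq 500. The titles place the animals in 2 groups, 3 bulls (intact males) and 3 steers (castrated males), and each title carries a different animal number, which is used here as the name of the animal. No number is shared between the groups, so nothing pairs a bull with a steer.

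The deposited values are raw read counts per gene, 1 file per animal, with no normalization by the authors. Per the submitters' processing notes, the tools were FastQC, TopHat2 version 2.0.2 and HTSeq version 0.5.3p3, and the genome build was UMD3.1. The annotation release, the strand setting and the overlap mode are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Each file holds 24616 rows of Ensembl gene IDs and 5 HTSeq summary rows. The summary rows name no gene and were kept out of library sizes and tests. They made up between 29.3% and 39.9% of all lines counted per file, most of it alignments to more than one place. Such reads are not counted for any gene, which lowers the counts of genes with near-identical copies.

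The files pair no ID with a gene name. The reference table supplied for names has 37063 rows, none with an Ensembl ID, and describes another assembly than the authors' build, so 0 of the 24616 IDs could be matched to a symbol or a position. No gene is therefore named, and no coordinates are given. Before the data were examined, 26 lists of genes had been fixed by symbol, covering lipid synthesis and storage, energy metabolism, fibre type, extracellular matrix, growth, androgen-related genes, proteolysis and the other cell types of a muscle sample. None of the 26 could be tested, and neither could a check of GC content or gene length. The rule for genes to print, also fixed before the data were examined, asked for genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM (counts per 1e6 counts of the library) in the higher group and no overlap between the groups, ordered by the size of the change. It was applied without its condition on the symbol and limited to 2 IDs per direction. The parts of the rule that drew on the lists or on fixed gene symbols were not used. Its last part, the 5 genes with the largest share of counts in each group, was used for values without IDs.

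Differences between bulls and steers were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling factors, the filterByExpr filter on low counts, robust dispersion estimates and Benjamini-Hochberg adjustment over all tested genes at 0.05. All 6 libraries entered 1 fit with the group as its only term. Log2 fold changes are coded bull minus steer, and their standard error was taken as the size of the log2 fold change divided by the square root of F. The filter kept 12769 genes, which held 99.9% of the gene counts. Correlations and spreads used log2 CPM with TMM factors and a prior count of 2. Single values per library were compared with exact 2-sided permutation tests, which for 3 animals against 3 cannot give a p below 0.1. Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma 3.58.1 (voom), a test against a fold of 1.2, a looser threshold and leaving out each animal in turn. No alternative was run for the gene lists, since the lists themselves were not tested.

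The fit was tested on simulated data for the comparison of bulls with steers, with 12769 genes at the real means and depths and 200 genes changed. With 1 spread for both groups it recovered 52 of 66 genes changed by 4-fold. It recovered 4 of 67 changed by 2-fold and 0 of 67 changed by 1.5-fold. Of its 65 calls in this simulation, 9 were unchanged genes, a larger share than the threshold on adjusted p allows on average. With a spread of its own for each group it recovered 55 of 66, 9 of 67 and 0 of 67, and 2 of its 66 calls were unchanged genes. In these simulations, changes of 2-fold and less were thus mostly missed at this number of animals. The adjusted p depends on how many genes differ, and the real fit called 524 genes. The shares missed and wrongly called in the real data can therefore be other ones.

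The gene counts summed to between 17027226 and 27490776 per library. A count of 0 allows up to 3 counts, which corresponds to at most 0.176 CPM in the shallowest library. Such floors and the intervals given for shares cover counting error only, since the labels describe no molecular identifiers.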

Results

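Muscle transcriptomes of 3 bulls and 3 steers of the Hanwoo breed were compared, which addresses how the longissimus muscle of castrated and intact males of this breed differs in gene expression. The bulls, numbered 20, 22 and 23, were all sampled at 746 days of age. Steers 439, 456 and 458 were sampled at 996, 950 and 930 days. Every steer was older than every bull, so castration and age cannot be told apart in any comparison between the groups.

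Sequencing depth overlapped between the groups. The gene counts amounted to 20146969 ± 1375232 per library in bulls and 23118040 ± 5439238 in steers (SD, n = 3; exact permutation p = 0.4). Steer 456 had the shallowest library with 17027226 and Steer 458 the deepest with 27490776. Reads were counted for 15932 ± 59.6 genes in bulls and 15580 ± 426 genes in steers (SD, n = 3; exact permutation p = 0.3). The fewest genes, 15127, were found in the deepest library, that of Steer 458. The 10 most abundant genes took 23.1% ± 1.16 of the gene counts in bulls and 20.5% ± 1.55 in steers (SD, n = 3; exact permutation p = 0.2). The 95% Wilson interval of this share was at most ± 0.0192 percentage points in any library. None of 9 such library measures differed between the groups after Benjamini-Hochberg adjustment (adjusted exact permutation p = 0.9 for each), in a design whose smallest possible p is 0.1.

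The bulls resembled one another more closely than the steers did. Across the tested genes, the correlation of log2 CPM was between 0.975 and 0.984 for the 3 pairs of bulls, between 0.928 and 0.967 for the 3 pairs of steers, and between 0.902 and 0.956 for the 9 pairs of a bull and a steer. These correlations run across genes, which are not independent replicates. The median SD of log2 CPM within a group was 0.18 in bulls and 0.39 in steers, a ratio of 2.19, and 80.4% of the tested genes had the larger SD in steers. Each animal was counted as 1 replicate, since the titles number the animals separately. The chi-square statistic per degree of freedom between 2 libraries was at least 34.9, so no pair looked like 1 library deposited under both names.

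**Figure D1:**
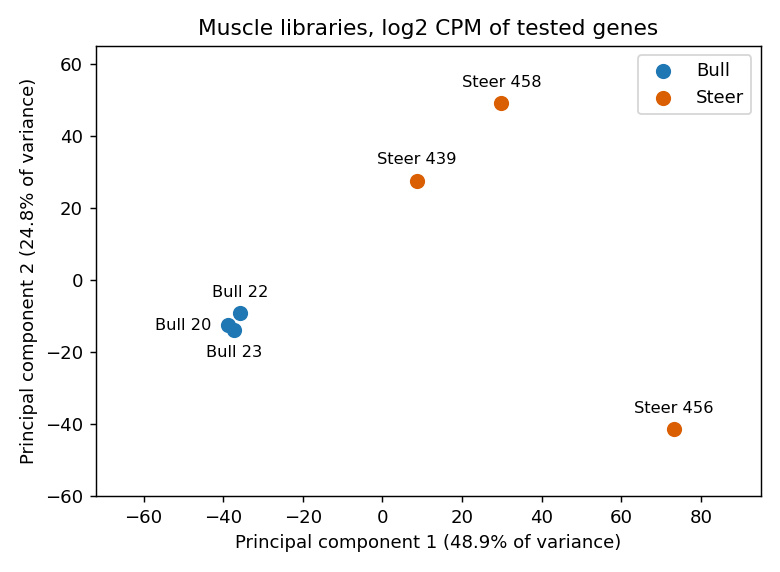
Principal component 1 (x axis, 48.9% of the variance) against principal component 2 (y axis, 24.8%) of log2 CPM over the tested genes, 1 point per animal, bulls in blue and steers in orange. The 3 bulls lie between -38.8 and -35.8 on component 1, while Steers 439, 458 and 456 lie at 8.70, 29.9 and 73.3.

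In bulls against steers, 524 of 12769 tested genes differed (4.10%; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 261 were higher and 263 were lower in bulls. Among the genes higher in bulls, 214 differed by at least 2-fold and 44 by at least 4-fold. Among the genes lower in bulls, 229 differed by at least 2-fold and 106 by at least 4-fold. The median log2 fold change was 1.34 in the higher genes and -1.68 in the lower genes, and the smallest change that passed was 0.73 in absolute size. In all 524 genes the 3 values of one group lay entirely above the 3 of the other. Over all tested genes this held for 3776 (29.6%), where chance gives 10% on average. Genes vary together across animals, so the share in a single split can lie far from 10%, and its spread was not measured. At an unadjusted p under 0.05 there were 2866 genes, 1379 higher and 1487 lower.

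The count of differing genes depended on single animals. Without Bull 20, Bull 22 or Bull 23 the same edgeR test called 10, 7 and 7 genes, and without Steer 458 it called 77. At an unadjusted p under 0.05 there were 1875, 2097, 1974 and 2741 genes in these fits, against 2866 with all animals, so the lost calls do not show that the differences were absent. Without Steer 439 or Steer 456 it called 995 and 1019 genes. DESeq2 called 1431 genes, 625 higher and 806 lower, among them all 524. The split between directions varied with the fit. Genes higher in bulls made up 49.8% of the calls with TMM scaling (261 of 524) and 66.6% with library size alone (247 higher, 124 lower). In the other fits of all 6 animals they made up 43.5% to 57.1%, and with 1 animal left out 39.9% to 53.8%.

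**Figure D2:**
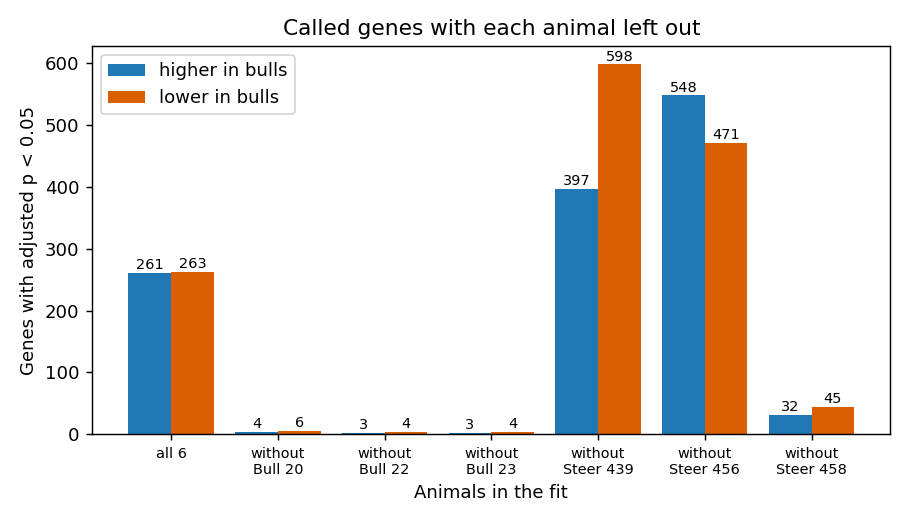
Number of genes with adjusted p under 0.05 (y axis) in the edgeR fit of all 6 animals and in the fits without each animal (x axis), with genes higher in bulls in blue and genes lower in bulls in orange. Each fit without a bull called at most 10 genes in all, against 524 with all animals.

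The genes lower in bulls were more often abundant than those higher in bulls. Of the 3192 tested genes with the highest mean abundance, 106 were lower and 61 higher in bulls. Of the other 9577 tested genes, 157 were lower and 200 higher. The odds ratio was 2.21 (Fisher's exact test, 2-sided p = 3.55e-05), a test that treats genes as independent. The mean runs over both groups, so a large change can itself place a gene among the most abundant. The genes lower in bulls had the larger changes (median log2 fold change -1.68 against 1.34), so the odds ratio may partly restate their size. Together, the 263 genes lower in bulls held 1.66% ± 0.112 of the counts in bulls and 6.89% ± 3.09 in steers (SD, n = 3). In single steers their share was 4.10% in Steer 439, 6.35% in Steer 458 and 10.2% in Steer 456, with 95% Wilson intervals of at most ± 0.0144 percentage points. The 261 genes higher in bulls held 1.203% ± 0.0474 of the counts in bulls and 0.460% ± 0.0351 in steers (SD, n = 3). These genes were chosen by the test on the same libraries, so the shares describe their abundance and are no separate evidence of a difference.

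**Figure D3:**
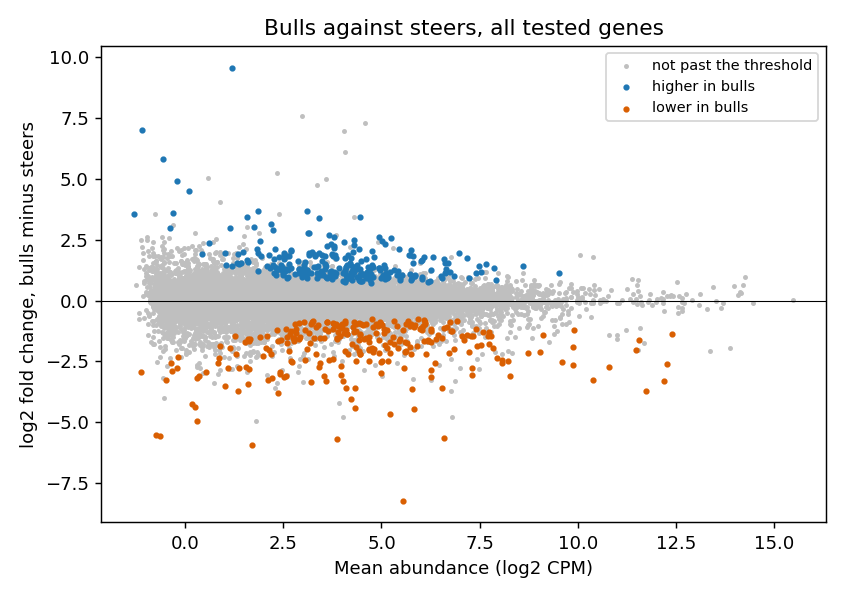
Log2 fold change of bulls minus steers (y axis) against mean abundance in log2 CPM (x axis) for each of the 12769 tested genes, with the 261 called higher in bulls in blue, the 263 called lower in orange and the others in grey. Orange points outnumber blue ones among the most abundant genes.

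The most abundant genes of the muscle did not pass the test. The gene with the largest share of counts was the same in both groups, with 4.71% ± 0.602 in bulls and 4.37% ± 1.35 in steers (SD, n = 3; edgeR adjusted p = 0.986). Neither it nor any other of the 5 most abundant genes of either group passed. The nearest was the second most abundant gene in steers, with 2.35% ± 1.25 of the counts there and 0.637% on average in bulls (log2 fold change -1.96, edgeR adjusted p = 0.0557).

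The gene IDs are not paired with names in the sources used here, so the genes with the largest changes under the fixed rule are given by Ensembl ID. Its condition of 5 CPM left out called genes with larger rises in bulls. One of them, ENSBTAG00000021565, had 4.44 ± 0.793 CPM in bulls (SD, n = 3) and 0 CPM in every steer. Its log2 fold change was 9.58 (edgeR adjusted p = 0.00997). With no read in any steer, the size of this change depends on how the fit treats a count of 0. It is thus no measured ratio, and a count of 0 allows up to 0.176 CPM in the shallowest library. ENSBTAG00000009012 was lower in bulls, with 92.9 ± 21.8 CPM in steers and 0.304 ± 0.113 CPM in bulls (SD, n = 3). Its log2 fold change was -8.22 ± 0.35 (SE), with an edgeR adjusted p of 9.25e-05, the smallest of all tested genes. It rested on between 1669 and 2785 reads per steer and between 4 and 9 reads per bull, and it passed the test in each fit that left out 1 animal. ENSBTAG00000003871 was also lower in bulls, with 0.0989 ± 0.102 CPM against 6.32 ± 4.77 CPM in steers (SD, n = 3). Its log2 fold change was -5.93 ± 0.85 (SE; edgeR adjusted p = 0.0205), and it had between 0 and 4 reads per bull.

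ENSBTAG00000019037 was higher in bulls, with 15.9 ± 7.67 CPM against 1.22 ± 0.106 CPM in steers (SD, n = 3). Its log2 fold change was 3.70 ± 0.38 (SE; edgeR adjusted p = 0.0101), and it passed in each fit that left out 1 animal. It did not pass in limma voom with weights per group (limma adjusted p = 0.0808). These weights allow for the larger spread of the steers across the tested genes as a whole. In this gene it was the bulls that spread more (SD 7.67 against 0.106 CPM), also in proportion to the group mean. ENSBTAG00000024826 was higher in bulls as well, with 6.57 ± 1.81 CPM against 0.482 ± 0.378 CPM in steers (SD, n = 3), a log2 fold change of 3.70 ± 0.60 (SE; edgeR adjusted p = 0.0260). In Steer 456 it had 1 read. ENSBTAG00000003871 and ENSBTAG00000024826 no longer passed without any one of the bulls or without Steer 458, with edgeR adjusted p up to 0.140 and 0.145. Their log2 fold changes in these fits were -5.40 to -6.92 and 3.56 to 4.16, against -5.93 and 3.70 with all animals. ENSBTAG00000024826 did not pass with weights per group either (limma adjusted p = 0.0537).

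**Figure D4:**
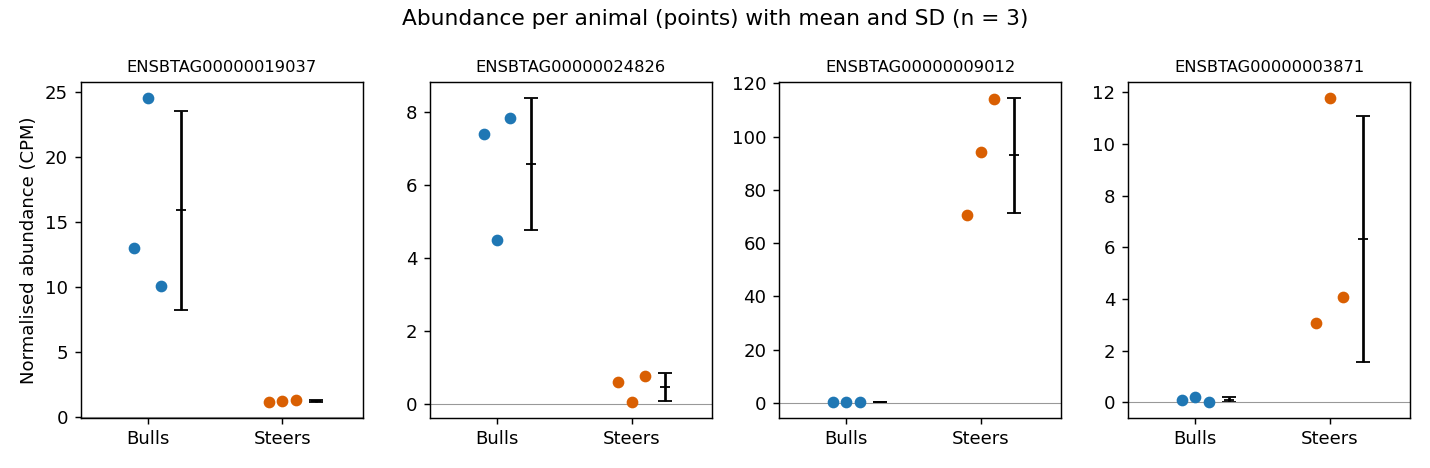
Abundance in CPM (y axis, a separate linear scale per gene) of the 4 gene IDs with the largest changes by the fixed rule, with 1 point per animal and the group mean and SD (n = 3) in black. The values of bulls and steers do not overlap for any of the 4.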

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

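The tests of wrong labels and of other splits were chosen after related results had been seen. The test of the shift through scaling and its bound were written after its values were known, and the folds of the calls lost with library size alone were examined after that loss was known. The tests of depth, of abundant genes and of Steer 456 were set out before their results were known, but the test of depth on the called genes was judged by its median and the 50% bound only after its range had been seen.

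The files also hold reads that no comparison above uses. Alignments to more than one place made up a median of 26.8% of all lines counted per library, between 16.9% in Steer 439 and 28.2% in Bull 22 (95% Wilson intervals of at most ± 0.0164 percentage points). Reads outside annotated genes made up a median of 11.3%, and reads over more than one gene a median of 0.438%. All of these lie far above the 3 reads that a count of 0 allows. No group of 4 or more animals exists, so no animal was tested as an outlier.

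The first pattern is the set of 524 genes called between bulls and steers. The real split called 524 genes and the other splits called at most 0, and 1 of the 10 splits reached the real count, but 10 splits are too few for a share under 0.05. Each other split also mixes bulls and steers in both groups, so any difference between them widens the spread within groups. Few calls were thus likely in those splits in any case, and the counts decide nothing. Depth is argued against as the cause: with all libraries thinned to the smallest total, a median of 90.2% of the called genes were called again (77.1% to 93.7% over 20 thinnings, the lowest short of the 80% set beforehand but above the 50% that depth as the cause would allow). A changing share of abundant genes is argued against as the whole cause: leaving TMM scaling out shifted the median log2 fold change of all genes by 0.086, and TMM factors spanned 0.277 log2 units over the libraries, against a smallest called change of 0.73 (that 99.4% were called again without the 10 most abundant genes tests little, since this hardly moved the scaling). Library size alone called 64.3% of the genes again (337 of 524) and 124 genes lower in bulls against 263. In the calls it lost, the median log2 fold change went from -1.54 to -1.48 in the 139 lower genes and from 1.25 to 1.33 in the 48 higher ones (middle 50% -2.24 to -1.12 and 1.04 to 1.80 before, -2.18 to -1.04 and 1.12 to 1.87 after). Their edgeR adjusted p rose from medians of 0.0402 and 0.0436 to 0.0593 and 0.0540, with a highest value of 0.0885. A change of scaling moves all genes by nearly the same amount. The small changes in fold therefore restate the shift of 0.086 and are no separate evidence against scaling. A wrong label stays open in general, because Steer 439 correlated on average slightly less with the other steers than with the bulls, by a margin of -0.0067. That margin came from Steer 456 (r = 0.928), since Steer 439 correlated at 0.967 with Steer 458 and at 0.953 to 0.956 with the bulls. The highest correlation of Steer 439 with a bull minus the lowest of a pair of bulls was -0.0189, and its nearest library was Steer 458. Both values argue against a bull's library under that label. Castration and age remain open and cannot be separated by this design. A batch of collection or library preparation that differed between the groups was not tested and stays open too.

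The second pattern is the larger spread among steers. Counting noise is argued against: at equal depth the ratio of the median SDs of steers and bulls had a median of 2.16 over 20 thinnings, with a range of 2.14 to 2.18. A single deviating steer is argued against as the whole cause, since the median SD of Steers 439 and 458 was 1.51 times that of the most different pair of bulls (0.24 against 0.16). What stays open is a biological difference, such as the steers' unequal ages where the bulls' ages were equal, or a batch of collection or library preparation, neither of which was tested.

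The third pattern is Steer 456, in which 628 genes were at least 2-fold above all other 5 animals, against 12 to 42 genes in each of the others. In the other direction it did not stand alone: 238 genes of Steer 456 and 227 of Steer 458 were at least 2-fold below all others, against 23 to 55 in the rest. Low depth is argued against: at equal depth its count was a median of 16.2 times that of the next animal, with a range of 14.4 to 18.8. Whether this animal lies further along the difference between steers and bulls stayed undecided: the difference of Steer 456 from Steer 439 correlated with that of Steer 458 from the bulls at r = 0.12 across genes, while its difference from Steer 458 correlated with that of Steer 439 from the bulls at r = -0.0429, and these comparisons share no library on their 2 sides. The remaining combination, Steer 458 from Steer 439 against Steer 456 from the bulls, gave r = 0.173. Built the same way with bulls and steers exchanged, the correlations were -0.0932, 0.0513 and 0.141. A value of 0.12 thus lay within the range found among the bulls, while 0.173 lay above their highest value. The order of the 2 bulls in each difference, and with it the sign of the correlation, was arbitrary. A share of another tissue in the sample may also raise such genes, which could not be examined without gene names.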

How the results depend on the processing

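The tests with edgeR's newer quasi-likelihood method, with weights per group, of single animals under DESeq2 and voom, and of Steer 456 and the spread under other settings were chosen after seeing the data. The 524 genes (261 higher, 263 lower in bulls) stayed within 1.5 times under DESeq2's size factors in edgeR, upper-quartile factors, no filter, a stricter filter, limma voom, weights per group and both quasi-likelihood methods, with 429 to 545 calls. The installed edgeR already uses the older method, so naming it changed nothing. Under library size alone the total was 371, with 124 genes lower. DESeq2 called 1431 genes (625 higher, 806 lower), the test against a fold of 1.2 called 333 (170 and 163), and an adjusted p under 0.10 called 1328 (631 and 697). With each animal left out, the total ranged from 7 to 1019, the higher genes from 3 to 548 and the lower genes from 4 to 598. In the simulation with a spread of its own for each group, leaving out a bull lowered 66 calls to between 33 and 35 and leaving out a steer gave 56 to 66. With 1 spread for both groups, 65 calls became 49 to 59 without a bull and 44 to 51 without a steer. Neither simulation gave the rise seen without Steer 439 or Steer 456, nor a fall as deep as that seen without a bull. Both drew each gene independently in each animal, so no animal was made to stand apart across many genes. They therefore cannot decide what lies behind the real changes. DESeq2 gave 618 to 778 calls without a bull and 1199 to 2002 without a steer. voom with group weights gave 499 calls with all animals and 7 to 528 with one left out, the lowest without Steer 458. The cause was not tested further. Of 18 alternatives, ENSBTAG00000009012 passed in all, ENSBTAG00000019037 in 17, ENSBTAG00000003871 in 14 and ENSBTAG00000024826 in 13. Among the 18, the older quasi-likelihood method and the looser threshold gave the same adjusted p as the main fit. A pass in these was therefore fixed in advance. The count of genes far above the others in Steer 456 was 617 to 737 under other factors and the stricter filter and 1044 with no filter, and the ratio of the SDs was 1.79 to 2.20. No paired analysis was possible because the groups share no animal numbers. A count of 0 allows up to 0.176 CPM in the shallowest library, and the simulations recovered few changes of 2-fold and less at this number of animals.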

Other observations

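The steers differed in how far they lay from the bulls. The root mean square log2 difference from the mean of the bulls was 0.67 in Steer 439, 0.83 in Steer 458 and 1.01 in Steer 456, and between 0.39 and 0.48 in the bulls, each set against the other bulls. The steer nearest to the bulls was the oldest, at 996 days, and the next was the youngest, at 930 days. With 1 animal per age, no trend with age can be read from these values. Of the 263 genes lower in bulls, 162 had their highest value among the steers in Steer 456, 73 in Steer 458 and 28 in Steer 439. Over all 12769 tested genes the numbers were 4931, 3871 and 3967. The 263 genes were chosen on these same libraries for higher values in steers, which the tested genes as a whole were not. Their counts are thus no separate evidence that Steer 456 lies further from the bulls.

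The 628 genes far above the other animals in Steer 456 held 9.17% of its gene counts and at most 2.80% of those of any other animal. In 406 of them (64.6%) the mean of the other 2 steers was above the mean of the bulls, against 48.9% of all tested genes, with a median log2 difference of 0.22. Of the 628 genes, 45 were among the 263 called lower in bulls.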
